A study of Mus musculus with 12 samples.

How the data were processed

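Astrocytes were sorted by fluorescence from the spinal cords of mice carrying an Aldh1l1-GFP reporter, per the labels, from control animals and animals with a conditional knockout (cKO) of the homeobox gene Nkx6-1. Per the labels' protocols, RNA was purified with a micro-scale column kit, and 10 ng of total RNA went into Trio RNA-seq V2 libraries sequenced in paired-end mode. The Trio kit amplifies cDNA and removes unwanted transcripts after library construction. The labels give the molecule as polyA RNA. Each of the 4 groups of sex and genotype had 3 labelled libraries. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

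Per the submitters' processing notes, the build was mm10 and the tools included FastQC 0.10.1, MultiQC 0.9, STAR 2.5.0a and DESeq2 1.20.0. The notes give no role or order for them. The gene annotation and the counting tool were not given in the sources used here, and whether reads were counted by strand was not given either. Genes overlapping a neighbour or sharing reads with a near-identical copy therefore carry an uncertain count.

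The deposited table holds gene symbols and, for each of the 12 libraries, a normalized signal per gene that was never negative. Within each library, 100% of the non-zero values were whole multiples of the library's smallest step, within a tolerance of 0.01 reads. The deposited values are therefore gene counts divided by 1 factor per library, and whole reads and depth were recovered from them. The deposited factors of the female libraries matched size factors computed within that sex, at a ratio of 1. Those of the male libraries were 0.9497 to 0.9631 of the size factors computed within males, and lay -0.0659 to -0.0539 on the log2 scale from factors computed over all 12 libraries. The set of libraries that the male factors were computed on was therefore not settled here. Relative to 1 common scaling, the factors of male libraries were shifted by -0.0412 on the log2 scale against those of female libraries, which places male values higher by that amount.

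The table had 24421 entries. In 27 of them the gene name had been turned into a date by spreadsheet software, giving 25 distinct strings, and these were tested but not named. A further 6546 entries were 0 in all libraries. No gene encoded in the mitochondrion was analysed here, and neither were Slc1a3, Ly6g or Trac. List members were matched by symbol alone, so Scn2a, Vxn and Cfap65, held under older symbols, did not enter their lists. Totals and shares of reads were taken over the recovered reads of all genes in the table, so they exclude reads assigned to no gene.

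Groups, contrasts, gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. That plan expected raw counts and edgeR, with limma-trend on log2(value + 1) named as the test if only normalized values were held. The latter was used. A single limma model with 1 mean per group was fitted to all 12 libraries, with an intensity trend and robust variance, and no replicate block. Contrasts were cKO minus control averaged over the sexes, in males and in females, the difference of those effects (female minus male), and female minus male among controls and among cKO libraries. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Genes with a value of at least 10 in at least 3 libraries were tested, 13269 in all. This filter was set after the table had been seen, because the planned one needed raw counts. The planned filter and edgeR test were run on the recovered reads as an alternative. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

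For each contrast the named genes were to be those passing with a mean log2 CPM of at least 1 and with separated groups in each sex covered. Where fewer than 5 passed, the 10 with the smallest unadjusted p were named as not passing. Symbols of predicted genes, Riken clones and Ensembl or LOC identifiers were counted but not named. Nkx6-1, up to 4 members per list with the smallest unadjusted p, sex-linked genes in the sex contrasts (Xist, Ddx3y, Eif2s3y, Kdm5d and Uty) and astrocyte reference genes (Aldh1l1, Gfap, Aqp4 and Slc1a2) were also named. Some genes that the rule takes are not reported here. Genes outside the rule are named as chosen after their values were seen.

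Lists of genes numbered 39 and covered astrocyte identity and functions, signalling, metabolism, stress, sex-linked genes and markers of other cell types. Lists with at least 5 tested members were tested, which left 37. The mitochondrially encoded list had 0 genes in the table and the Y-linked list had 4 tested genes, so these were described only. Lists overlap: 17 of the 25 tested astrocyte identity genes and 6 of the 24 oligodendrocyte markers were also in another list. Lists were tested with limma's camera, which asks whether members moved more than other genes, at a preset inter-gene correlation of 0.01. The correlation estimated per list and fry were the alternatives. Members were also counted as adjusted over the list alone. Coordinates are 1-based and come from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes.

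The test of single genes was tried on simulated data drawn from the real means and depths with a biological coefficient of variation of 0.606. Changes were planted only in genes with a mean of at least 50 normalized counts, and all libraries were drawn independently. The rates therefore do not cover lower genes such as Nkx6-1, nor a sample that enters under more than 1 label. Of 50 genes per size planted in the average of the sexes (13123 genes), 2% of 2-fold, 46% of 4-fold, 96% of 8-fold and 100% of 16-fold changes were called. In males alone (13101 genes) these were 0%, 6%, 50% and 92%. Of unchanged genes, 0.031% were called in each. The list test was tried on other data, made of the gene means plus the real deviations of libraries from their group means. The libraries were put in a random order, which keeps the real correlation between genes. With glycolysis genes shifted by log2 1 in the male cKO group, camera gave that list an adjusted p of 2.96e-30 at the preset correlation. It also called 10 other, unplanted lists. With an estimated correlation the planted list had an adjusted p of 0.0187 and 0 others were called.

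Alternatives covered the count tools (edgeR with TMM or RLE factors, DESeq2, limma-voom), 1 scaling for all libraries, pseudocounts, filters, model terms, thresholds, a replicate block and each library left out in turn. DESeq2 and edgeR were run on the recovered reads. Fits without libraries whose labels or target gene reads were doubtful and the common scaling were added after the data had been seen. So was the use of recovered reads for the edgeR test with TMM factors that had been planned for raw counts. Library pairs were compared by a chi-square of their recovered reads over genes with at least 20 reads in the pair. Limits for 0 reads take 3 reads per library as the floor. Such floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The intervals given for changes of list means come from fits over the libraries and measure the spread between them. For 3 libraries against 3, an exact permutation test cannot give a two-sided p under 0.1, and the means of the lists per library were compared in that way.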

Results

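Gene expression was measured in sorted spinal cord astrocytes of male and female mice, to ask how loss of the homeobox transcription factor Nkx6-1 from astrocytes affected each sex. Male control, male cKO, female control and female cKO groups each had 3 labelled libraries. Mean depth was 6298047 reads in genes in male controls (range 2246412 to 9054934) and 3999787 in male cKO libraries (2773280 to 5078344). It was 5849820 in female controls (4109601 to 7124347) and 3754906 in female cKO libraries (2679412 to 5662377). Between 13611 and 15255 genes had at least 1 read. The 45S ribosomal RNA precursor Rn45s took 20.9% to 40.6% of the reads. Its share was 28.9% ± 8.58 in male controls, 34.6% ± 8.25 in male cKO, 30.8% ± 9.11 in female controls and 31.3% ± 6.46 in female cKO (SD, n = 3 each). The sorted cells carried many transcripts of other cell types. Aldh1l1, whose reporter was used for the sort, had 32.1 to 330 normalized counts. Those of the myelin gene Mbp were 43566 to 405303 over the 12 libraries, against 1334 to 8529 for the astrocyte water channel Aqp4 and 7373 to 53991 for the glutamate transporter Slc1a2. Of the immediate early gene Fos there were 1672 to 3313, of the neuronal gene Snap25 218 to 1788 and of the microglial gene C1qa 16.3 to 173.

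Nkx6-1 (chromosome 5, 101658139 to 101664996, minus strand) was near the limit of detection in every group, so it checked the genotype labels weakly. Male control libraries had 3, 9 and 2 reads, and female control libraries had 19, 7 and 12. Among cKO libraries, replicates 1 and 2 of both sexes had 0 reads, while replicate 3 had 18 reads in males and 19 in females. In normalized counts these were 25.6 and 28.3, above every control library, whose highest value was 15.2 in female control replicate 3. Read counts of 0 allowed up to 2.56 and 6.23 normalized counts in male cKO replicates 1 and 2, and 2.09 and 5.79 in those of females. Mean normalized counts were 3.18 ± 1.47 in male controls and 8.55 ± 14.8 in male cKO, and 10.3 ± 5.80 in female controls and 9.44 ± 16.4 in female cKO (SD, n = 3). The limma log2 fold changes were -0.41 in males (SE 1.57, adjusted p = 0.972) and -1.70 in females (SE 1.57, adjusted p = 1.00). The male direction turned with edgeR on recovered reads (1.43), and without male cKO replicate 1 or 2 (0.38 each). The labels do not say which part of the gene was removed, and reads from the remaining part would be counted as Nkx6-1. The libraries labelled cKO replicate 3 are thus not shown by this gene to lack it, in either sex, and they enter every cKO direction given here.

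Sex-linked transcripts separated all libraries but 1. Xist, the RNA that silences an X chromosome, had 0 to 2 reads in male controls, 15 and 0 in male cKO replicates 1 and 3, and 2757 to 13074 in the female libraries. Y-linked genes together had 422 to 2117 reads in those 5 male libraries and 0 in all 6 female libraries. The library labelled male cKO replicate 2 had 3546 Xist reads and 0 Y-linked reads, so it did not match its sex label. Its reads also matched those of the female cKO replicate 2 library closely, with a chi-square of 1.054 per degree of freedom over genes with at least 20 reads in the pair. The other 65 pairs of libraries had values of 14.5 to 116, and pairs within a group 20.1 to 63.8. Across genes, the pair's log values had a correlation of 0.971, against at most 0.876 for any other pair. The 2 libraries thus hardly exceeded sampling noise and count as 1 sample. Because their labels put them in different groups, all 12 libraries were kept in the planned model, and values without the library labelled male cKO replicate 2 are given beside the calls it changes and the medians of passing lists that it moves by over 1.5 times.

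**Figure D1:**
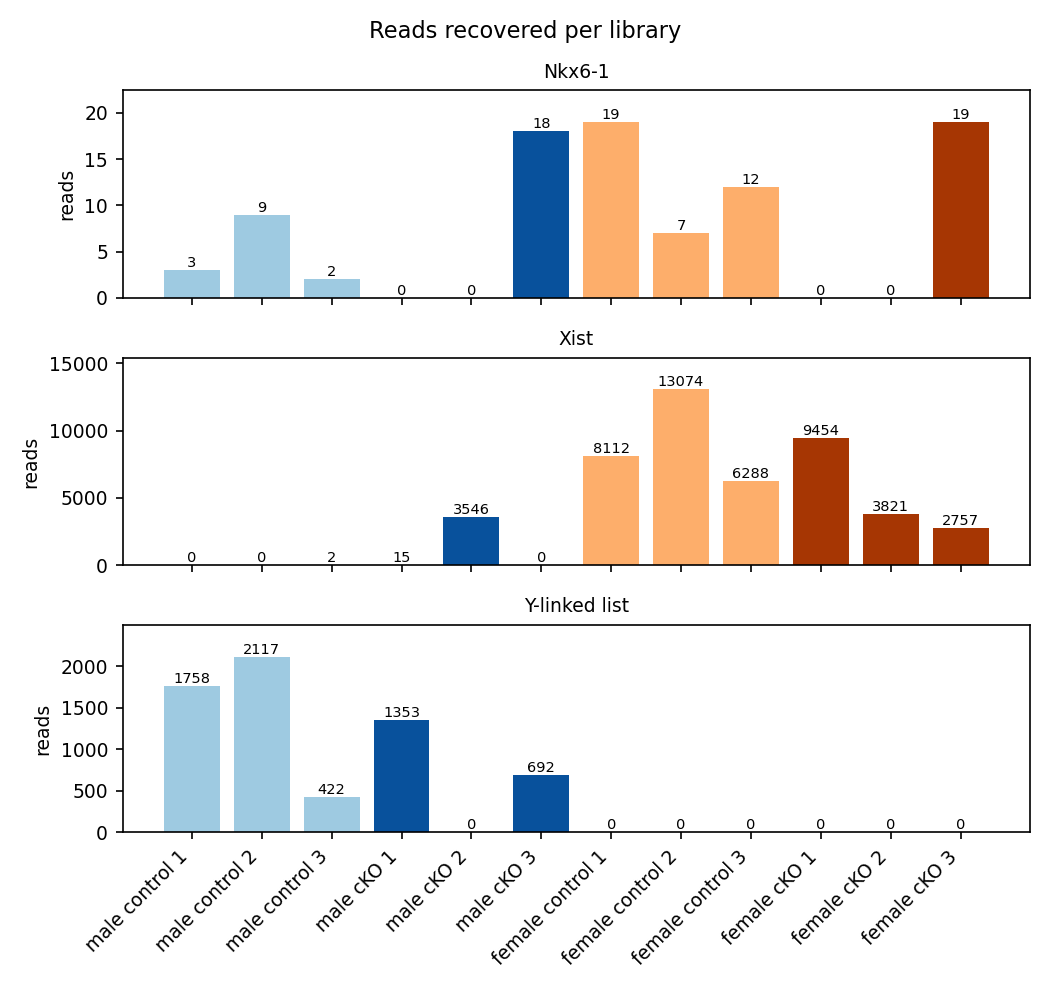
Reads recovered in each of the 12 libraries (bars, reads on the vertical axis) for Nkx6-1, Xist and the Y-linked list. The library labelled male cKO replicate 2 has 3546 Xist reads and 0 Y-linked reads, and both cKO replicate 3 libraries have Nkx6-1 reads (18 and 19).

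The first comparison asked what differed between cKO and control astrocytes when the sexes were averaged (6 libraries labelled cKO against 6 controls). Slc16a4, a member of the monocarboxylate transporter family (chromosome 3, 107291230 to 107312115), averaged 43.1 ± 13.4 normalized counts in male controls and 225 ± 48.7 in male cKO, and 54.0 ± 7.95 and 159 ± 111 in females (SD, n = 3). Nrp2, a receptor for semaphorins (chromosome 1, 62703285 to 62818695), averaged 112 ± 35.6 and 305 ± 124 in males and 124 ± 42.3 and 332 ± 82.6 in females. St18, a zinc finger gene of the myelin transcription factor family (chromosome 1, 6487231 to 6860940), averaged 608 ± 245 in male controls and 206 ± 54.6 in male cKO, and 638 ± 171 and 293 ± 136 in females. Their log2 fold changes in limma were 1.83 (SE 0.37), 1.42 (SE 0.30) and -1.35 (SE 0.28), and each had an adjusted p of 0.339, so none passed. The fatty acid elongase gene Elovl7 had -0.90 (SE 0.20), Ypel2 -1.34, Vprbp -1.43, Kazn -1.24, Pik3c2b -1.08 and the condensin gene Ncapd3 -1.63, also without passing. The lysosomal enzyme gene Naglu completed the 10 genes with the smallest p. It averaged 35.8 ± 20.5 in male controls and had 0 reads in all 3 male cKO libraries, at least 8.23-fold lower against a floor of 3 reads per library. In females it averaged 18.5 ± 4.80 and 5.87 ± 7.72. Slc16a4, Nrp2, St18, Elovl7, Naglu and Ypel2 had separated cKO and control libraries in both sexes, in the same direction in each. These genes were chosen for a small p in the same comparison, and the closely matching cKO replicate 2 libraries enter both sexes. Separation in both sexes is therefore not independent support.

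**Figure D2:**
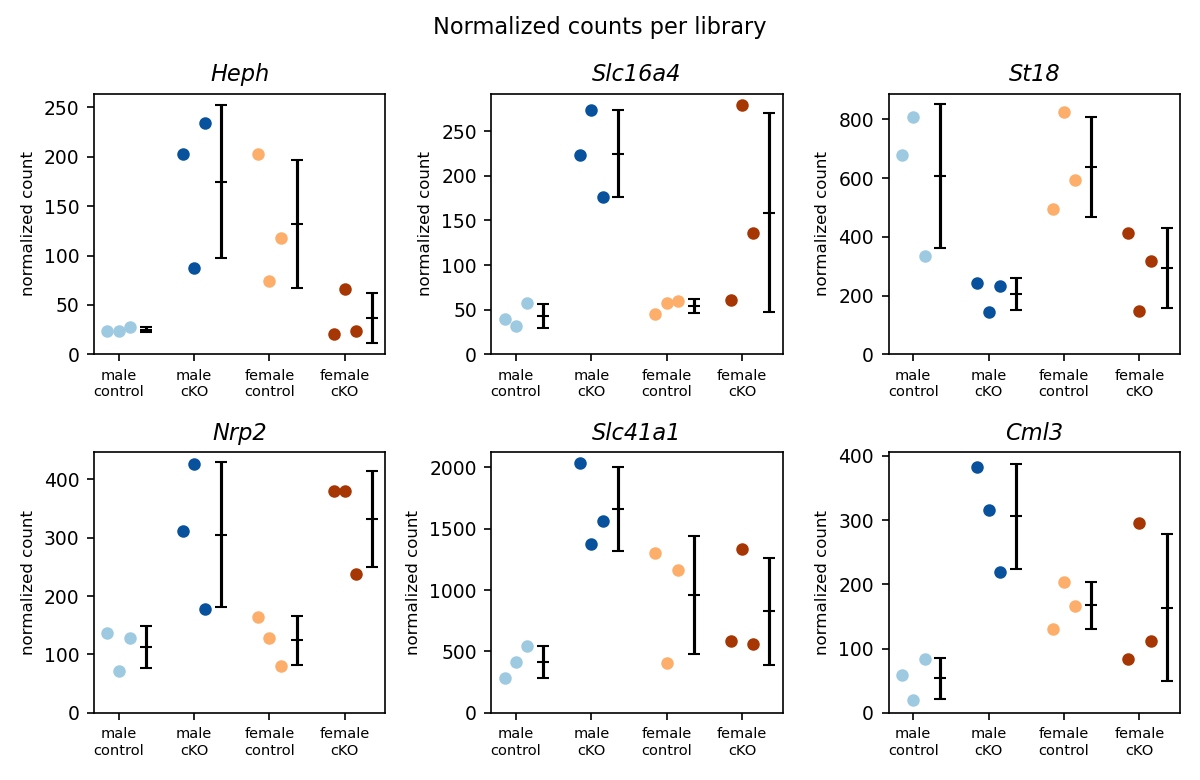
Normalized counts (vertical axis, from 0) of 6 genes in each library (points), with the mean and SD of each group of 3 labelled libraries (bars to the right). Slc16a4, Nrp2 and St18 separate cKO from control libraries in both sexes, while Heph averages 24.9 and 175 in male controls and male cKO and 132 and 36.6 in females. None of the 6 passed the limma test, and the closely matching cKO replicate 2 libraries enter both sexes.

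In limma, 0 of the 13269 genes passed for the average of the sexes, with 1195 at an unadjusted p under 0.05 where chance gives 663. edgeR also called 0 genes, with 1233 at an unadjusted p under 0.05, and DESeq2 called 41, of which 19 were higher and 22 lower. DESeq2 was run only on all 12 libraries, and so counted the closely matching cKO replicate 2 libraries as separate samples. Without the library labelled male cKO replicate 2, limma called 0, with 1123 at an unadjusted p under 0.05. Over the alternatives the adjusted p of Slc16a4 was 0.000926 to 0.828, the lowest with DESeq2. Leaving out both cKO replicate 3 libraries gave 1 gene, the growth factor family member Fgf11 (2.62, limma adjusted p = 0.0229). It falls outside the naming rule and was chosen after its value was seen. That fit counts the closely matching cKO replicate 2 libraries as separate samples. With only the library labelled male cKO replicate 2 left out, Fgf11 had 1.65 (limma unadjusted p = 0.00256) and did not pass.

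Astrocyte identity genes were higher as a group in the average of the sexes, with 25 of 25 members higher and a median log2 fold change of 0.84. No member passed over all genes and 0 passed adjusted over the list alone. The camera adjusted p was 1.86e-14 at the preset correlation, and the adjusted p = 0.404 with an estimated correlation. Among its members, the growth factor receptor Fgfr3 had 0.93, the acyl-CoA synthetase Acsbg1 1.04 and Ndrg2 1.06. Oligodendrocyte markers were lower, with 20 of 24 members lower and a median of -0.70, and 12 passed adjusted over the list alone against 0 over all genes. Their camera adjusted p was 2.83e-10, and the adjusted p = 0.404 with an estimated correlation. Of the cytosolic ribosomal protein genes 41 of 42 were higher, with a median of 0.35 and 0 passing in either way (camera adjusted p = 4.06e-09, adjusted p = 0.418 with an estimated correlation). Cell cycle genes were lower in 22 of 25 members, with a median of -0.88 and 1 passing adjusted over the list alone (camera adjusted p = 0.000353, adjusted p = 0.404 with an estimated correlation). Blood cell markers had a median of -2.11 beside them and did not pass (camera adjusted p = 0.211). Endothelial markers were higher in 20 of 21 members, with a median of 0.47 (camera adjusted p = 0.000578, adjusted p = 0.562 with an estimated correlation).

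The averaged effect passed in 17 of 37 lists with camera at the preset correlation, 14 higher and 3 lower. The other higher lists were neuropeptides and secreted signals (median 0.50, with 4 members passing adjusted over the list alone), oxidative phosphorylation (0.30), glutamate uptake (0.35), glycolysis (0.25), potassium, calcium and water homeostasis (0.33), and Notch, Shh, BMP and Wnt targets (0.35). They also included GABA and glycine handling (0.43), interferon response (0.39), G protein coupled receptors (0.39), synaptogenic factors (0.25, 2 adjusted over the list alone) and vesicle release (0.24, 1 adjusted over the list alone). Where no such count is given it was 0. Their adjusted p = 0.404 to 0.558 with an estimated correlation. Oligodendrocyte precursor markers were lower (median -0.20, camera adjusted p = 0.0357, adjusted p = 0.68 with an estimated correlation). Vesicle release and precursor markers no longer passed without the library labelled male cKO replicate 2 (camera adjusted p = 0.0585 and 0.102). Without it the median of GABA and glycine handling was 0.18 and that of synaptogenic factors 0.37. Extracellular matrix genes (median 0.41), fibroblast markers (0.64) and lipid transport genes (0.26) passed without it, at camera adjusted p-values of 0.000441, 0.00125 and 0.0425, with an adjusted p = 0.47, 0.47 and 0.324 with an estimated correlation. With all 12 libraries these 3 lists had medians of 0.00305, 0.19 and 0.23 and did not pass. No list call of any comparison here held with an estimated correlation. At the preset correlation, astrocyte and endothelial markers were thus higher and oligodendrocyte markers lower in the same comparison.

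The comparison within males asked what the cKO changed in that sex (3 libraries labelled male cKO against 3 male controls, 1 of the former not matching its sex label). Astrocyte identity genes were higher in the cKO group, 25 of 25 members, with a median log2 fold change of 1.40. Aqp4 averaged 2380 ± 1199 normalized counts in controls and 8253 ± 411 in cKO, and Slc1a2 averaged 14770 ± 8617 and 47300 ± 6468 (SD, n = 3). Oligodendrocyte markers were lower in 22 of 24 members, with a median of -0.97. The myelin genes Mag and Mog had log2 fold changes of -1.30 (SE 0.35) and -1.37 (SE 0.39), while the more abundant Mbp had 1.78 (SE 0.94). None of these genes passed over all genes.

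In males the camera adjusted p of the astrocyte identity list was 7.77e-25 at the preset correlation, and its adjusted p = 0.224 with an estimated correlation. Over 20 alternatives it was 2.13e-32 to 0.224. Of its 25 genes, 17 passed adjusted over the list alone and 0 over all genes, among them Acsbg1 (1.92, SE 0.47), the orphan receptor Gpr37l1 (1.38, SE 0.36), Fgfr3 (1.36, SE 0.37) and the aldolase Aldoc (1.63, SE 0.43). The reference genes Aldh1l1 and Gfap had 0.98 and 1.90 (SE 0.82). The oligodendrocyte list had a camera adjusted p of 2.27e-10, with an adjusted p = 0.234 with an estimated correlation, and 12 of its 24 genes passed adjusted over the list alone. Without the library labelled male cKO replicate 2 the medians were 1.47 for astrocyte identity and -0.99 for oligodendrocyte markers. Per library, the mean log2 value of the astrocyte list was 9.19 ± 0.637 in male controls and 10.6 ± 0.126 in male cKO (SD, n = 3). All 3 cKO libraries lay above all 3 controls, and the exact permutation p was 0.1, the smallest that 3 against 3 allows.

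**Figure D3:**
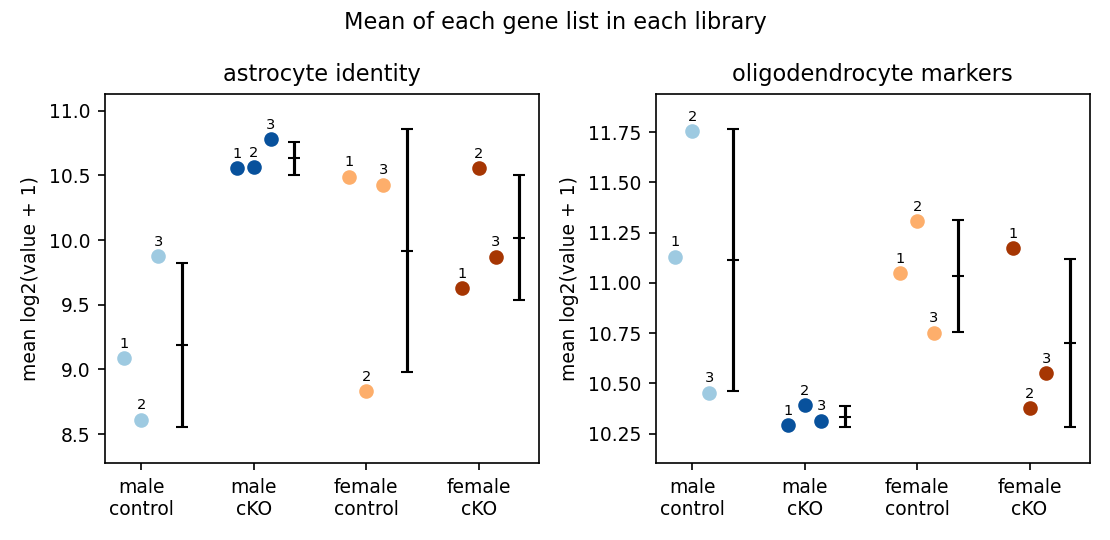
Mean log2(value + 1) of the astrocyte identity and oligodendrocyte marker lists in each library (points, numbered by replicate), with the mean and SD of each group of 3 labelled libraries (bars). The male groups separate in the astrocyte list, at 9.19 ± 0.637 and 10.6 ± 0.126, and the female groups overlap, at 9.92 ± 0.939 and 10.0 ± 0.483.

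Glycolysis, ribosomal protein and oxidative phosphorylation genes were also higher as groups in male cKO libraries. The list mean of cholesterol synthesis genes was not (difference -0.128, exact permutation p = 0.6). Glycolysis and glycogen genes were higher in 24 of 26 members, with a median of 0.59. Adjusted over the list alone 2 passed, the glycogen phosphorylase Pygb (1.22) and Aldoc (1.63), while the phosphofructokinase Pfkm had 1.29 and did not pass. Their camera adjusted p was 2.43e-07, and the adjusted p = 0.224 with an estimated correlation. Ribosomal protein genes (38 of 42 higher, median 0.48) and nuclear genes of oxidative phosphorylation (31 of 37 higher, median 0.42) had camera adjusted p-values of 8.32e-07 and 1.99e-05, with an adjusted p = 0.456 and 0.374 with an estimated correlation. Cell cycle genes were lower in 22 of 25 members, with a median of -1.30 and 0 passing adjusted over the list alone (camera adjusted p = 4.13e-05, adjusted p = 0.224 with an estimated correlation). They included the replication helicase gene Mcm2 (-2.66, SE 0.84), the sliding clamp gene Pcna (-1.31, SE 0.43) and the mitotic kinase gene Bub1 (-3.57, SE 1.52). Blood cell markers had a median of -2.77 in males and did not pass (camera adjusted p = 0.341). Of the 12 libraries, male control replicate 3 had the highest mean log2 value of both lists, 6.1 for cell cycle genes and 8.21 for blood cell markers. In male control replicates 1 and 2 these were 5.23 and 5.53, and 4.40 and 1.94. Oligodendrocyte precursor markers were lower in 17 of 18 members, with a median of -0.54 (camera adjusted p = 0.00081, adjusted p = 0.456 with an estimated correlation). Endothelial markers were higher in 19 of 21, with a median of 0.59 (camera adjusted p = 0.000153, adjusted p = 0.503 with an estimated correlation). Neither of these lists had a member passing adjusted over the list alone.

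Lists of astrocyte functions passed at the preset correlation in males as well. Potassium, calcium and water homeostasis genes had a median of 0.61 and 10 of 32 passing adjusted over the list alone, with the potassium channel Kcnj16 at 1.31 (SE 0.34), the bicarbonate transporter Slc4a4 at 1.79 (SE 0.55) and the calcium channel Orai1 at -2.75. Glutamate uptake and glutamine cycle genes had a median of 0.74 and 6 of 16 passing adjusted over the list alone, including the mitochondrial glutamate carrier Slc25a18 (2.09, SE 0.57) and the cystine and glutamate exchanger Slc7a11 (1.65, SE 0.51). Notch, Shh, BMP and Wnt targets had a median of 0.69 and 1 of 28 passing adjusted over the list alone, with the Notch target Hes5 at 4.90 (SE 1.27), the hedgehog transducer Smo at 1.62 (SE 0.50) and the receptor Ptch1 at 1.10 (SE 0.36). Camera adjusted p-values of these lists were 6.57e-05, 8.2e-05 and 0.000111, and each had an adjusted p = 0.224 with an estimated correlation. Neuropeptides and secreted signals (median 0.51, Cxcl14 at 2.13) and spinal astrocyte position genes (median 0.63, Epha4 at 1.45) had camera adjusted p-values of 0.00042 and 0.0136, both with an adjusted p = 0.224 with an estimated correlation. They had 4 of 22 and 3 of 19 members passing adjusted over the list alone.

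GABA and glycine handling (median 0.66, 3 of 27 adjusted over the list alone), G protein coupled receptors (0.61, 2 of 27) and regional patterning transcription factors (0.34, 2 of 23) had camera adjusted p-values of 0.00081, 0.00081 and 0.03 in males. Their adjusted p = 0.271, 0.234 and 0.234 with an estimated correlation. Patterning genes included the hedgehog effectors Gli3 (2.19, SE 0.56) and Gli2 (1.76), Sox9 (1.22) and Nkx2-9 (-1.50). Synaptogenic and phagocytic factors had a median of 0.28, with 1 of 26, Sparc, passing adjusted over the list alone and the adhesion gene Nrcam at 0.84 without passing (camera adjusted p = 0.0398, adjusted p = 0.412 with an estimated correlation). Interferon response genes had a median of 0.33 (camera adjusted p = 0.03, adjusted p = 0.503 with an estimated correlation), and no longer passed without the library labelled male cKO replicate 2 (camera adjusted p = 0.0642). Without that library the medians of synaptogenic factors and G protein coupled receptors were 0.65 and 0.37. Extracellular matrix genes and fibroblast markers had medians of -0.05 and -0.04 with all libraries and turned to 0.68 and 0.81 without it, where they passed (camera adjusted p = 0.000687 and 0.0133, adjusted p = 0.497 and 0.609 with an estimated correlation). Lipid transport (median 0.41) and astrocyte morphology and adhesion genes (0.19) also passed only without it (camera adjusted p = 0.0209 and 0.0339, adjusted p = 0.229 and 0.497 with an estimated correlation). No member of any list passed over all genes in males.

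**Figure D4:**
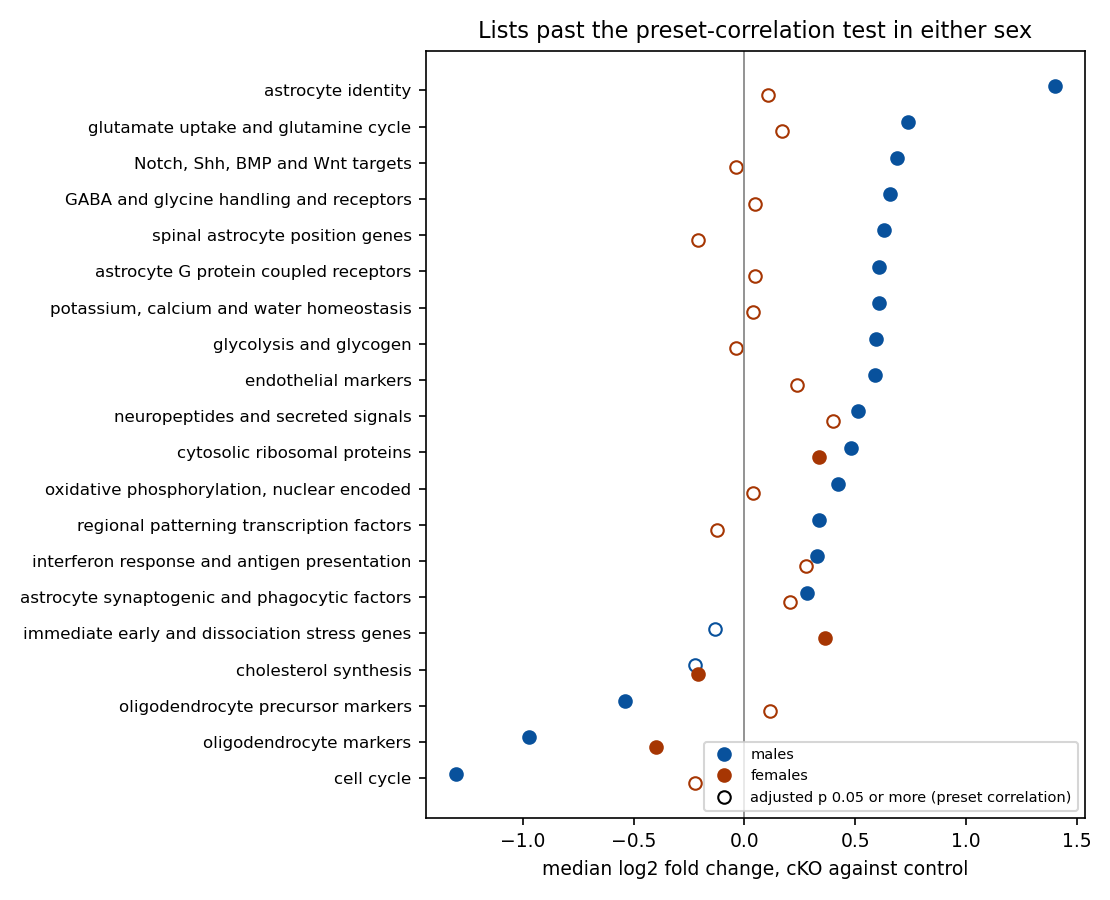
Median log2 fold change, cKO against control (horizontal axis), of the 20 lists that passed camera at the preset correlation in males or in females. Filled points passed in that sex and open points did not. Astrocyte identity is at 1.40 in males and 0.11 in females, and no list passed with an estimated correlation.

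Among the genes with the smallest p in males were Slc41a1, a magnesium transporter (chromosome 1, 131827493 to 131848865; 413 ± 133 in controls, 1659 ± 341 in cKO), and Gabbr1, a subunit of the GABA-B receptor (chromosome 17, 37045966 to 37075067; 318 ± 9.54 and 825 ± 142). Their log2 fold changes were 2.04 (SE 0.41) and 1.36 (SE 0.31). Cml3 (54.0 ± 32.0 and 306 ± 81.9; 2.66, SE 0.53), Igdcc4 (2.06, SE 0.42), Slc16a4 (2.38, SE 0.53), the phosphodiesterase Pde7b (1.84, SE 0.42) and Heph (2.64, SE 0.60) were further higher genes, and Nkain1 (-1.72, SE 0.39) and Vprbp (-2.11) were lower. None of these genes passed in limma, where each had an adjusted p of 0.306.

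In limma, 0 genes passed in males, with 1170 at an unadjusted p under 0.05 where chance gives 663. edgeR called 0, with 1160 at an unadjusted p under 0.05, and DESeq2 called 17 (12 higher, 5 lower). Male cKO and control libraries were separated for 13.6% of genes (1807), where chance gives 10%. A fit on only the 6 male libraries called 11 genes, all higher, with log2 fold changes of 1.56 to 2.53, among them Elovl2, Slc41a1, Slc6a11, Aqp4, Aldoc, Slc1a2 and Gja1 (Elovl2 was chosen after its value was seen). That fit called 0 without the library labelled male cKO replicate 2. In the model of all groups, leaving out female control replicate 2 gave 31 genes, all higher, and 10 of the 11 were among them. That library is not in the male comparison and acts through the shared spread.

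In females (3 cKO against 3 controls), ribosomal protein genes were higher in 38 of 42 members, with a median log2 fold change of 0.34. Immediate early and dissociation stress genes were higher in 32 of 35, with a median of 0.36. Among them were Junb (1.08, SE 0.35) and the mRNA decay factor Zfp36 (0.72, SE 0.32). The list mean of female control replicate 2, 8.254, lay above those of female cKO replicates 1 and 2, 8.003 and 7.995. In female controls 1 and 3 it was 7.506 and 7.53, and the exact permutation p was 0.3. Oligodendrocyte markers were lower in 20 of 24, with a median of -0.40, and cholesterol synthesis genes in 21 of 26, with a median of -0.21, including Dhcr7 (-1.17, SE 0.41) and the regulator Srebf2 (-0.88, SE 0.33). Astrocyte identity genes had a median of 0.11, with 17 of 25 higher and a camera adjusted p of 0.655. Female control replicate 2 had a list mean of 8.83, against 10.5 and 10.4 in the other female controls, both above the cKO mean of 10.0. The reference genes Aqp4, Slc1a2, Gfap and Aldh1l1 had 0.25, 0.18, 0.11 and -0.30. The positive signs rested on female control replicate 2, with 1334, 7373 and 353 normalized counts of Aqp4, Slc1a2 and Gfap. The other female controls had 7699 and 6503, 39675 and 41923, and 1695 and 1336. These all lay above the cKO means of 5139, 28314 and 1222.5.

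These 4 lists passed camera at the preset correlation in females, at adjusted p-values of 0.000153, 0.000195, 0.00154 and 0.0422, and each had an adjusted p = 0.991 with an estimated correlation. No member of them passed over all genes and 0 passed adjusted over the list alone. The count was 7 without female control replicate 2, 9 without female control replicate 3, 7 without female cKO replicate 1, and 2 without female cKO replicate 3. Fibroblast markers (median 0.48) also passed without the library labelled male cKO replicate 2, at a camera adjusted p of 0.0496 and an adjusted p = 0.915 with an estimated correlation. Among single genes the zinc finger gene Zscan29 averaged 218 ± 137 normalized counts in controls and 34.8 ± 9.66 in cKO (-2.42, SE 0.61). The mitochondrial transcription factor Tfam averaged 14.3 ± 12.8 and 70.9 ± 16.3 (2.54, SE 0.71), and the mitochondrial carboxykinase Pck2 12.4 ± 10.2 and 78.8 ± 35.7 (2.74, SE 0.77). Pcbd1 (4.33, SE 1.15), the splicing factor Sf3a1 (-1.55, SE 0.44), Ythdc2 (-1.70, SE 0.48), Wdfy2 (-2.77, SE 0.79), D10Wsu102e (1.64), Nrp2 (1.44, SE 0.42) and Igsf11 (-1.04, SE 0.31) completed the 10, all with a limma adjusted p of 1.00. limma called 0 genes in females, with 471 at an unadjusted p under 0.05 where chance gives 663. edgeR called 0, with 474 at an unadjusted p under 0.05, and DESeq2 called 4, all lower: Zscan29 and the neutrophil granule genes Ngp, Elane and Ltf. Among the female libraries Ngp had reads in control replicate 2 alone. Without female control replicate 2, limma called 1 gene, Serpinf1 (3.13). Elane, Ltf and Serpinf1, and Dmrta1 further on, were named after their values were seen.

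The difference between the female and the male effect was tested as an interaction, since the series is titled for sex-specific regulation. Heph, a ferroxidase of iron export (chromosome X, 96455359 to 96574485), averaged 24.9 ± 2.53 normalized counts in male controls and 175 ± 77.3 in male cKO, and 132 ± 65.3 in female controls and 36.6 ± 25.2 in female cKO (SD, n = 3). Its interaction was -4.55 on the log2 scale (SE 0.85), with a limma adjusted p of 0.344 and 0.000167 to 1 over the alternatives. Among lists, astrocyte identity had the lowest median interaction, -1.41, with 0 members higher and 25 lower, which means a larger male than female change. Glycolysis genes had a median of -0.64 with 23 of 26 lower, and Notch, Shh, BMP and Wnt targets had -0.77 with 19 of 28 lower. Oligodendrocyte markers had a median of 0.56 with 22 of 24 higher, and immediate early genes had 0.46 with 30 of 35 higher.

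Camera adjusted p-values of these interactions at the preset correlation were 2.96e-19, 1.37e-07, 0.00162, 0.00162 and 0.000592. Their adjusted p = 0.33, 0.33, 0.33, 0.598 and 0.525 with an estimated correlation. In all, 17 lists passed at the preset correlation (5 higher, 12 lower), with 0 members passing over all genes and 0 passing adjusted over the list alone, and 12 passed without the library labelled male cKO replicate 2. Without female control replicate 1 the count was 11. Within these lists, Hes5 had an interaction of -5.25, Sox9 -1.55 and Acsbg1 -1.75, none passing. In limma 0 genes passed the interaction, with 358 at an unadjusted p under 0.05 where chance gives 663. edgeR called 0, with 441 at an unadjusted p under 0.05, and DESeq2 called 1, Heph. Without the library labelled male cKO replicate 2, limma called 0, with 731 at an unadjusted p under 0.05. Without both cKO replicate 2 libraries it called Heph (-5.50, limma adjusted p = 0.0469).

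Across the 13269 genes, male and female log2 fold changes had a Pearson correlation of 0.225 (covariance 0.172), with genes not being independent replicates. Simulated unchanged groups that shared 1 library in the way the 2 closely matching libraries do gave 0.165 (covariance 0.126, 100 simulations). The observed correlation was 0.0805 (covariance 0.0697) without the library labelled male cKO replicate 2, 0.101 without female control replicate 2 and 0.00772 without female cKO replicate 2.

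Female controls were compared with male controls for the baseline sex difference (3 against 3). Library numbers ran from 1 to 11 in the libraries labelled male and from 13 to 18 in those labelled female. What the numbers stand for was not settled here. A difference in handling that follows them cannot be told apart from sex, in controls or in cKO libraries. Ddx3y was at least 204-fold lower in female controls, Uty at least 69.0-fold, Kdm5d at least 54.5-fold and Eif2s3y at least 36.8-fold, against a floor of 3 reads per library. Xist averaged 1.43 ± 2.48 normalized counts in male controls and 6750 ± 1566 in female controls (log2 fold change 11.89). In the model of all 12 libraries, which includes the library labelled male cKO replicate 2, these 5 genes did not pass (limma adjusted p 0.463 to 1.00). Without it they were the 5 genes that passed, at limma adjusted p-values of 6.71e-06 to 0.0132. Apart from them, Heph (2.24), Cml3 (1.81), the prolactin receptor Prlr (3.65), Maml2 (-1.16) and Tmod1 (-2.54) had the smallest p.

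Astrocyte identity genes were higher in female than in male controls, 24 of 25 members, with a median of 0.82. Their camera adjusted p was 1.59e-15, and the adjusted p = 0.389 with an estimated correlation. Female control replicate 2 had a list mean of 8.83, against 10.5 and 10.4 in the other 2 female controls. X genes that escape inactivation were higher in 8 of 9 members, with a median of 0.39 and 1 gene, Xist, passing adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.389 with an estimated correlation). Fibroblast markers were lower in 17 of 20 members, with a median of -0.73 (camera adjusted p = 0.000416, adjusted p = 0.551 with an estimated correlation), and immediate early genes in 31 of 35, with a median of -0.28 (camera adjusted p = 0.000546, adjusted p = 0.499 with an estimated correlation). Glycolysis genes were higher in 22 of 26, with a median of 0.20 (camera adjusted p = 0.000416, adjusted p = 0.389 with an estimated correlation). Of the 37 lists 14 passed at the preset correlation, 10 higher and 4 lower, and 2 passed without female control replicate 1 and 6 without female control replicate 3. The other 9 were potassium, calcium and water homeostasis (0.21), Notch, Shh, BMP and Wnt targets (0.21), spinal astrocyte position (0.43), patterning factors (0.20), G protein coupled receptors (0.40), GABA and glycine handling (0.24), pericyte markers (0.34, 2 adjusted over the list alone), blood cell markers (-2.77) and cell cycle genes (-0.41). Their adjusted p = 0.389 to 0.551 with an estimated correlation. Extracellular matrix genes (-0.37) and neuropeptides and secreted signals (0.40) passed only without the library labelled male cKO replicate 2 (camera adjusted p = 0.032 and 0.0317, adjusted p = 0.703 and 0.457 with an estimated correlation). limma called 0 genes, with 226 at an unadjusted p under 0.05 where chance gives 663. edgeR called 0, with 271 at an unadjusted p under 0.05, and DESeq2 called 0. Without female control replicate 2, limma called 1 gene, Serpinf1 (-3.15).

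Among cKO libraries, female against male (3 against 3 as labelled), X genes that escape inactivation were higher in 9 of 9 members, with a median of 0.55. Astrocyte identity genes were lower in females in 25 of 25 members, with a median of -0.63, the opposite direction to the controls. Their camera adjusted p-values were 9.41e-05 and 3.16e-07, with an adjusted p = 0.514 and 0.669 with an estimated correlation. Oligodendrocyte markers were higher in 21 of 24, with a median of 0.42, and microglia and macrophage markers in 18 of 26, with a median of 0.30 (camera adjusted p = 9.41e-05 and 0.00618, both with an adjusted p = 0.669 with an estimated correlation). None of these 4 lists had a member passing adjusted over the list alone, and 10 lists passed in all, 4 higher and 6 lower. The others were glycolysis (-0.35), oxidative phosphorylation (-0.36), ribosomal proteins (-0.27), glutamate uptake (-0.42), potassium, calcium and water homeostasis (-0.45, with Orai1 passing adjusted over the list alone) and oligodendrocyte precursor markers (0.33). Their adjusted p = 0.669 to 0.726 with an estimated correlation. Without the library labelled male cKO replicate 2, ribosomal proteins, precursor markers and potassium, calcium and water homeostasis no longer passed (camera adjusted p = 0.481, 0.293 and 0.125). Extracellular matrix genes (median -0.80), fibroblast markers (-0.93) and synaptogenic factors (-0.47) then passed instead, at camera adjusted p-values of 0.000568, 0.00131 and 0.0212, with an adjusted p = 0.763, 0.763 and 0.538 with an estimated correlation. The medians of X genes that escape inactivation, microglia markers and ribosomal proteins were then 0.84, 0.67 and -0.14. Single genes with the smallest p were Heph (-2.30), Orai1 (3.47), the thymidylate kinase Dtymk (-2.62), the transhydrogenase Nnt (-1.93), Agpat1 (-1.77), Zdhhc15 (2.73) and Ccar2 (2.12), with Ddx3y, Kdm5d and Uty at least 95.8-fold, 27.8-fold and 31.6-fold lower in females. limma called 0 genes, with 417 at an unadjusted p under 0.05 where chance gives 663. edgeR called 0, with 487 at an unadjusted p under 0.05, and DESeq2 called 4 (Elane, Ngp, Ltf and Dmrta1). The closely matching cKO replicate 2 libraries lie in opposite groups of this comparison. With the library labelled male cKO replicate 2 left out, limma had 1077 genes at an unadjusted p under 0.05 where chance gives 655. edgeR then had 1105 where chance gives 702. Without the library labelled male cKO replicate 2, limma called 6 genes, at adjusted p-values of 2.99e-05 to 0.0249. They were Xist (10.62), Orai1 (4.85), Ddx3y, Kdm5d, Uty and Eif2s3y. On the same libraries edgeR called the 5 sex-linked genes among them and not Orai1.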

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

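The tests of library identity, of the astrocyte and oligodendrocyte difference and of the Rn45s share, and the splits for gene counts, were chosen only after the result was seen, and the splits for list counts were not.

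The library labelled male cKO replicate 2 matched the female cKO replicate 2 library, at a chi-square of 1.054 per degree of freedom. That value is consistent with one RNA or library under both labels, since the closest other pair had 14.5. A swap between a male and a female cKO library is argued against by 0 Y-linked reads in every library labelled female. A mixture of male and female RNA is argued against as well, since 0 Y-linked reads allow at most 0.582% of the level in the other male cKO libraries. Whether a tube, a library or a table column was exchanged stays open, and no biological explanation was tested.

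Astrocyte identity genes were higher and oligodendrocyte markers lower in the libraries labelled male cKO. The library labelled male cKO replicate 2 was not the sole cause, as the astrocyte median was 1.47 without it. As a linear covariate, the Rn45s share left a list difference of 1.07 (95% interval 0.37 to 1.77), against 1.44 (0.27 to 2.61) without it. These fits count the matching libraries as separate samples. They also cannot exclude a property of the samples that the share tracks only in part. With the library labelled male cKO replicate 2 left out, the differences were 1.21 (0.42 to 1.99) with the covariate and 1.48 (0.05 to 2.91) without. A larger share of astrocytes that lowers every other cell type alike stays open, because the endothelial minus oligodendrocyte change of 1.36 had an interval from -0.67 to 3.38. Splits of the 6 male libraries are too few for a share under 0.05: the real one gave 18 lists, as did the highest other, 2 of the 10 splits. Within the male cKO group the astrocyte list did not follow the Nkx6-1 reads. Its mean was 10.8 in replicate 3, with 18 reads, and 10.6 in each of replicates 1 and 2, with 0 reads. Reads from a remaining part of the gene would be counted too. An effect of Nkx6-1 loss on astrocyte genes remains a hypothesis that may account for the difference. It cannot be told apart here from a different purity of the sort.

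The mean of the astrocyte identity list also differed between libraries of one group, from 8.83 to 10.5 in female controls. Over 11 libraries (without the library labelled male cKO replicate 2) it correlated with the Rn45s share within groups at r = 0.875 (permutation p = 0.00478, adjusted p = 0.0268 over 6 relations), which is consistent with library composition acting on both. Pooled over groups, r was 0.758 (permutation p = 0.00918, adjusted p = 0.0268), rho 0.736 (permutation p = 0.0134, adjusted p = 0.0268), and r 0.634 without the 2 libraries farthest from the median share. Depth gave r = -0.507 (permutation p = 0.112), rho = -0.509 (permutation p = 0.113), -0.735 without the 2 farthest and -0.597 within groups (permutation p = 0.109), all with an adjusted p of 0.113. Both the Rn45s share and the list could follow another property of the samples, such as RNA quality or sort purity, which was not measured here, or a biological difference between the animals.

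Lists whose cKO effect differed between the sexes in the interaction test, at the preset correlation alone, had these median log2 differences, female minus male. They were -1.41 for astrocyte identity, -0.64 for glycolysis and glycogen, -0.58 for potassium, calcium and water homeostasis, -0.38 for oxidative phosphorylation, and -0.77 for Notch, Shh, BMP and Wnt targets. They were -0.72 for glutamate uptake and the glutamine cycle, -0.78 for spinal astrocyte position, -0.23 for G protein coupled receptors, -0.63 for GABA and glycine handling and -0.41 for regional patterning factors. Pericyte and smooth muscle markers had -0.74 and neuropeptides and secreted signals -0.33. Positive medians were 0.46 for immediate early genes, 0.56 for oligodendrocyte markers, 0.45 for oligodendrocyte precursor markers, 0.84 for cell cycle genes and 0.58 for microglia and macrophage markers. Camera adjusted p-values were 2.96e-19 to 0.0489, and the adjusted p = 0.33 to 0.688 with an estimated correlation. Precursor markers, G protein coupled receptors, GABA and glycine handling, pericyte markers and neuropeptides no longer passed without the library labelled male cKO replicate 2 (camera adjusted p = 0.07 to 0.0935), with medians of -0.38 for pericyte markers and -0.53 for neuropeptides.

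Named genes whose cKO libraries all lay on one side of the controls in males and all on the opposite side in females had these interactions, none passing in limma. Heph had -4.55 (2.64 in males and -1.90 in females, adjusted p = 0.344). The hedgehog co-receptor Boc had -1.26 (0.96 and -0.30), the smooth muscle myosin Myh11 -3.30 (1.37 and -1.93) and the lipopolysaccharide co-receptor Cd14 2.79 (-1.46 and 1.33). Lrrc27 had 5.97 (-3.30 and 2.67) and Clrn1 6.44, whose fitted value depends on the pseudocount because all male cKO libraries were at 0 reads, at least 5.16-fold lower than the male controls. Of all tested genes, 25 separated in opposite directions in the sexes, 0.188% against 0.219% in simulated unchanged genes with the matching library in both sexes. With that library left out of the males these were 117 genes, 0.882% against 0.992% by chance.

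For the average of the sexes, as many lists as the real 17 came in 11 of 100 splits, with up to 23 in another, and for the interaction in 16 of 100 (real 17, highest other 21). Chance could not be excluded for these 2 counts. A real count of 0 genes is reached by every split, so splits for gene counts decide nothing. They gave 100 of 100 for the average (real 0, highest other 192) and 100 of 100 for the interaction (real 0, highest other 157). In males they gave 10 of 10 (real 0, highest other 0). In females they gave 10 of 10 for genes (real 0, highest other 0) and 9 of 10 for lists (real 4, highest other 19). Between the sexes they gave 10 of 10 for genes in controls (real 0, highest other 58), 4 of 10 for lists in controls (real 14, highest other 22) and 10 of 10 for genes in cKO libraries (real 0, highest other 44). For lists, 10 splits cannot give a share under 0.05. The highest counts of 44 to 192 genes were not typical, since the median of the other splits was 0 genes in every comparison. What sets the splits with many genes apart was examined only for the matching pair of libraries. Among cKO libraries, splits with that pair in one group gave 0 to 44 genes, and the 6 splits with the pair in different groups gave 0. In the other comparisons the pair was never in one group, since splits were made within each sex or among controls. For the average and the interaction, the matching libraries could still fall on the same side or on opposite sides. Whether that sets the counts, and what the splits with many genes share, was not tested.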

How the results depend on the processing

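Fits that leave out chosen libraries, the edgeR fit with TMM factors and the common scaling were chosen after the data had been seen. The named genes and passing lists that were followed through the alternatives (no list between the sexes in cKO) kept their direction and side of the threshold in 2739 of 3138 alternatives. They lost the threshold in 315, gained it in 83 and turned in 1, the median of microglia and macrophage markers in the interaction, -0.05 without both cKO replicate 3 libraries. Lists that did not pass were not followed, and some turned without male cKO replicate 2, among them extracellular matrix genes (0.68) and fibroblast markers (0.81) in males. The 14 design results stayed within their limits in 288 of 350 alternatives, moved in 51 and turned in 11. No gene passed in the main limma fit, so a named gene that again fell short, or a gene count that stayed at 0, counted as kept. Most list alternatives used the preset correlation. These tallies therefore do not measure robustness. At this depth and spread, 2-fold changes were seldom called in simulation, and Nkx6-1 had no value under the stricter filter (11235 genes) or without both cKO replicate 3 libraries. For values that moved below, the cause was not tested, except where fewer libraries were used.

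DESeq2 called 41 genes for the average of the sexes, 17 in males, 4 in females, 1 in the interaction and 4 between the sexes in cKO libraries, against 0 in limma. A fit on only the libraries of the contrast called 11 in males and 5 between the sexes in controls. Without both cKO replicate 3 libraries 1 gene passed on average. Without both cKO replicate 2 libraries 1 passed in the interaction, and 5 and 5 between the sexes in controls and cKO. Without male cKO replicate 2 and both cKO replicate 3 libraries these were 14 in males (a lone male cKO library, assumed to vary like the other groups), 5 in controls and 24 in cKO. edgeR without male cKO replicate 2 called 5 and 5. Without male cKO replicate 2 and female control replicate 2, 11 passed in males, 1 in females, 6 in controls and 6 in cKO. Leaving out each library in turn gave 0 to 31 genes in males, 0 to 1 in females, 0 to 0 on average and in the interaction, 0 to 5 in controls and 0 to 6 in cKO.

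The correlation of male and female cKO log2 fold changes was 0.00772 to 0.309 with each library left out. It was 0.0437 without both cKO replicate 2 libraries, 0.320 without both cKO replicate 3 libraries, 0.0352 without these 3 doubtful libraries (male cKO 2 and both cKO 3) and -0.00459 without male cKO replicate 2 and female control replicate 2. Nkx6-1 in males turned to 1.44 (edgeR, RLE), 1.43 (edgeR, TMM), 1.45 (DESeq2), 0.18 (pseudocount 5) and 1.98 (edgeR without male cKO replicate 2). It was 0.38 without both cKO replicate 2 libraries, without male cKO replicate 2 and female control replicate 2, and in males alone without male cKO replicate 2. Leave-one-out values were -1.99 to 0.38 in males and -3.33 to -0.89 in females.

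With an estimated correlation and with fry, 0 lists passed on average, in males, in females, in the interaction and between the sexes in controls. Without both cKO replicate 3 libraries, and without those and male cKO replicate 2, 1 list passed in females, and without both cKO replicate 3 libraries 10 passed in the interaction. Leave-one-out counts were 14 to 19 on average, 16 to 21 in males, 2 to 9 in females, 11 to 22 in the interaction and 2 to 20 in controls. With the replicate number as a block, 0 genes passed in all 6 comparisons, and 17, 18, 5, 18 and 16 lists. Deviations of equally numbered libraries correlated at -0.107 to 0.0405, which gave no sign of pairing by number. With 3 libraries per group these values cannot exclude a pairing. The block moved no count by over 1.5 times.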

Other observations

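The libraries and genes singled out here were chosen only after their values were seen, while the tests of the lists were planned.

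Blood cell genes varied between single libraries more than between groups. The mean log2 value of the 7 tested blood genes was 8.21 in male control replicate 3, 6.31 in male cKO replicate 1, 5.53 in male control replicate 1 and 5.33 in female control replicate 2, and 1.21 to 2.82 in the other 8. The neutrophil granule gene Ngp had 159 normalized counts in female control replicate 2 and 0 reads in the other 5 female libraries. The list median was -2.77 in males (camera adjusted p = 0.341) and -1.38 in females (adjusted p = 0.412), or -0.78 with the genes at 0 placed at their bound. Microglia and macrophage markers had their highest list mean, 7.65, in female cKO replicate 3, against 5.75 to 6.89 in the other 11 libraries. Fibroblast markers ranged from 6.55 in the library labelled male cKO replicate 2 to 9.27 in male cKO replicate 1.

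Lists of astrocyte reactivity and adhesion did not pass the averaged comparison with camera. Reactive astrocyte genes had a median of 0.26 and a camera adjusted p of 0.253, and astrocyte morphology and adhesion 0.06 (0.253). Glutamate receptors had 0.12 (0.404), glucocorticoid response -0.05 (0.659), Hox genes 0.05 (0.937) and sex steroid receptors and response -0.11 (0.994), with 1 member of the last passing adjusted over the list alone. Neuron markers had 0.01 (0.229), pericyte markers -0.12 (0.963), ependymal markers -0.09 (0.963) and Schwann cell markers -0.20 (0.963). With the library labelled male cKO replicate 2 left out, Schwann cell markers turned to 0.16 and neuron markers to -0.06. Glutamate receptors then had 0.05, Hox genes 0.02, sex steroid receptors and response -0.009 and glucocorticoid response -0.08, and none of these 6 lists passed (camera adjusted p = 0.346 to 0.956). Among lipid transport genes in males, the lipid exporter Abcg1 had -1.68 and the apolipoprotein genes Clu and Apoe 1.47 and 1.43. None passed over all genes, and 2 of 19, Abcg1 and Clu, passed adjusted over the list alone.

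Genes with separated cKO and control libraries in both sexes and in the same direction numbered 128, 0.965% of those tested, against 0.785% in simulated unchanged genes with the matching library in both sexes. With that library left out of the males these were 176 genes, 1.33% against 1% by chance. In females alone 9.11% of genes (1209) were separated, against 10% by chance.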
